A study of Homo sapiens with 6 samples.

How the data were processed

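RIP-seq libraries of 786-O cells were analysed, 3 of RNA recovered with IGF2BP2 and 3 of input. Groups and replicate numbers came from the sample titles. The labels give the RNA as poly(A) RNA and, per the labels' protocols, libraries were made with a Tru-seq kit from RNA isolated with RNAiso Plus. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10a, featureCounts and DESeq2 with the build hg38. The gene annotation, the strand setting and how reads with several alignments were treated are not given in the sources used here, so genes that overlap others or have near-identical copies are uncertain.

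The authors deposited a table of raw read counts per gene symbol for 20020 genes and a table of FPKM values for the same genes. Dividing the deposited counts by the FPKM values and by each column's total gave 1 length per gene, whole to within 2.47e-10 nt in each library with reads and the same whole number in all of them. The deposited FPKM are therefore the counts scaled by that length and by the column totals of this table. These lengths served as exonic gene lengths. Some are very long, as for *SMAD2* at 35403 nt, as lengths that join the exons of several isoforms would be. Every value column was matched to a sample by its title and no column was left over. Of the symbols, 19304 matched the current RefSeq gene table (GRCh38.p14) directly and 111 more through a synonym, and 19197 of the former are protein-coding. Coordinates are the spans of that table, on the same primary assembly as hg38. Small noncoding RNA genes are not rows of the table, so 1 list fixed for them had no member. A total of 2525 genes had no read in any library.

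Genes were kept by filterByExpr with its defaults, which left 12856 genes. Counts were scaled with TMM and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, robust fit) with the group as the only term, in R 4.3.3. Calls have a Benjamini-Hochberg adjusted p under 0.05, and positive fold changes are higher in RIP. Levels are CPM after TMM scaling, with the SD over 3 libraries. SEs of log2 fold changes come from the spread of log2 CPM between libraries. The common biological coefficient of variation was 4.55%. With 25773819 to 44045835 reads per library, counting error was small for all but the least expressed genes. On simulated counts for the 12856 genes, with 200 changed in each of 10 simulations of RIP against input, the test recovered 63.0% of genes changed 1.25-fold, 83.6% at 1.5-fold, 91.5% at 2-fold and 99.8% at 4-fold, and 6.43% of its calls were false, above the nominal 5%. A simulated shift of 1 list was called and none of the 19 unchanged lists was. A simulated length trend was removed, from a rho of 0.82 to 0.012. Only 200 genes changed per simulation, while 82.7% were called in the data, so the shares of recovered and false calls need not hold there. Genes were simulated independently, so the list check could not show the effect of correlation between genes.

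Before the data were examined, 23 gene lists, the design, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera compares a list with the other genes. Counts of called members are from the adjustment over all genes. Adjusted over the list alone they were the same for all lists but the TGF-beta response genes (12 enriched, 13 depleted), integrins (8 and 5) and zinc finger genes (253 and 70). Some lists share members, and *PABPC1* counts in both lists that hold it.

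The genes named were the 10 most enriched and the 10 most depleted called genes with a mean of at least 5 CPM, with a gene symbol that is no pseudogene or clone name and with all RIP libraries beyond all inputs. To these were added the IGF2BP genes, *TGFBR1*, *TGFBR2*, *SMAD2*, *SMAD3* and *SMAD4*, and for each list up to 2 called members per direction with at least 5 CPM, or the 2 of highest level where none was called. *XIST* and Y-linked genes were passed over.

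No replicates agreed within sampling noise. The chi-square per gene between replicates, which is near 1 for sampling noise alone, was 3.42 to 8.46.

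Alternatives were RLE, upper-quartile and library-size scaling, scaling without ribosomal protein and mitochondrial genes, DESeq2 1.42.0, limma-voom, no filter or a filter of 5 CPM in 3 libraries, a test against a 1.5-fold change, the replicate block, a correction for gene length, limma on log2(FPKM + 1) or log2(FPKM + 0.1), and leaving out each library. The effect of scaling on the list medians was added after the data were seen, as were gene families picked by symbol. The length correction fitted a robust loess curve (span 0.3) of each library's log2 CPM deviation on log2 length and used it as offsets. GC content was not examined, as no sequence was used.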

Results

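RNA immunoprecipitation sequencing (RIP-seq) was carried out in 786-O cells, an established human clear cell renal carcinoma line. RNA recovered with IGF2BP2, a cytoplasmic RNA-binding protein that has been described as a reader of N6-methyladenosine (m6A), was sequenced in 3 libraries, and input RNA in 3 more. The series title places the experiment in a study of TGF-beta to SMAD signalling and m6A. The comparison therefore asked which transcripts were over- or under-represented with IGF2BP2 relative to input, and where the TGF-beta and SMAD transcripts stood. A pull-down with a nonspecific antibody was not analysed here, so the values are RIP over input and hold whatever any antibody or bead would bring down.

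The count table held 37872917, 44045835 and 33872621 reads in RIP libraries 1, 2 and 3, and 26345064, 27226405 and 25773819 in input libraries 1, 2 and 3. Nearly all named rows were protein-coding genes, and between 15417 and 15786 genes had at least 1 read in a library. Libraries of one kind resembled each other closely, with Pearson correlations of log2 CPM (read counts scaled to library size) between 0.994 and 0.995 across genes. Correlations between a RIP and an input library lay between 0.917 and 0.921. Cytosolic ribosomal protein genes took 0.982%, 0.962% and 0.962% of the reads in the RIP libraries and 3.39%, 3.64% and 3.62% in the inputs. Mitochondrially encoded mRNAs took 10.9% to 11.5% in RIP and 12.5% to 13.9% in input. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

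The IGF2BP2 fraction differed from input over most of the expressed transcriptome. Transcripts of *IGF2BP2* itself and of its paralog *IGF2BP3* were about 2-fold higher in RIP. Many transcripts of TGF-beta and SMAD signalling were also higher, whereas mRNAs of ribosomal proteins, histones and the respiratory chain were lower. After the correction for gene length the TGF-beta and SMAD list and the histones no longer passed camera (adjusted p = 0.465 and 0.104). With an estimated correlation between genes none of these lists passed camera (adjusted p = 0.269 for each). Before adjustment the camera p in that setting ran from 0.0436 for the respiratory chain to 0.0808 for ribosomal proteins. Its degrees of freedom come from the 6 libraries and are few, so these failures cannot show whether correlation between genes explains the shifts. Of 12856 genes tested with edgeR's quasi-likelihood test, 5232 were enriched and 5403 depleted at a Benjamini-Hochberg adjusted p under 0.05, which is 82.7% of the genes. A change of 2-fold or more was seen for 1943 enriched and 2527 depleted genes. The enriched number was only 1194 with library size alone as the scale and 672 to 910 in fits on log2 FPKM. FPKM values are also scaled by library totals, so these are not separate checks. In 83.1% of the tested genes all 3 RIP libraries lay beyond all 3 inputs, against 10% expected by chance. The quartiles of the log2 fold change were -0.79 and 0.68. Fold changes are relative to the average gene after TMM scaling. The median gene stood at -0.02 on the log2 scale, at -0.11 with upper-quartile scaling and at -0.26 with library size alone as the scale, where the calls split into 4115 enriched and 6476 depleted. Enriched genes made up 49.2% of the calls with TMM, 38.9% with library size alone and 38.5% to 38.7% in fits on log2 FPKM.

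*IGF2BP2* mRNA (chromosome 3, 185643130 to 185825042 on GRCh38) stood at 263 ± 4.09 normalised CPM in RIP and 121 ± 2.97 in input (mean ± SD, n = 3 each), a 2.16-fold enrichment with an edgeR adjusted p of 1.36e-18. *IGF2BP3* (chromosome 7, 23310209 to 23470491) rose 2.15-fold, from 54.6 ± 1.19 to 117 ± 2.59 CPM. *IGF2BP1* (chromosome 17, 48996558 to 49056145) had a low level, at 3.22 ± 0.261 CPM in RIP and 3.38 ± 0.290 in input, and did not pass the edgeR test (adjusted p = 0.677). After removal of the trend of enrichment with gene length it was called, at a log2 fold change of -0.53. These are levels of mRNA and do not show how much protein was recovered.

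**Figure D1:**
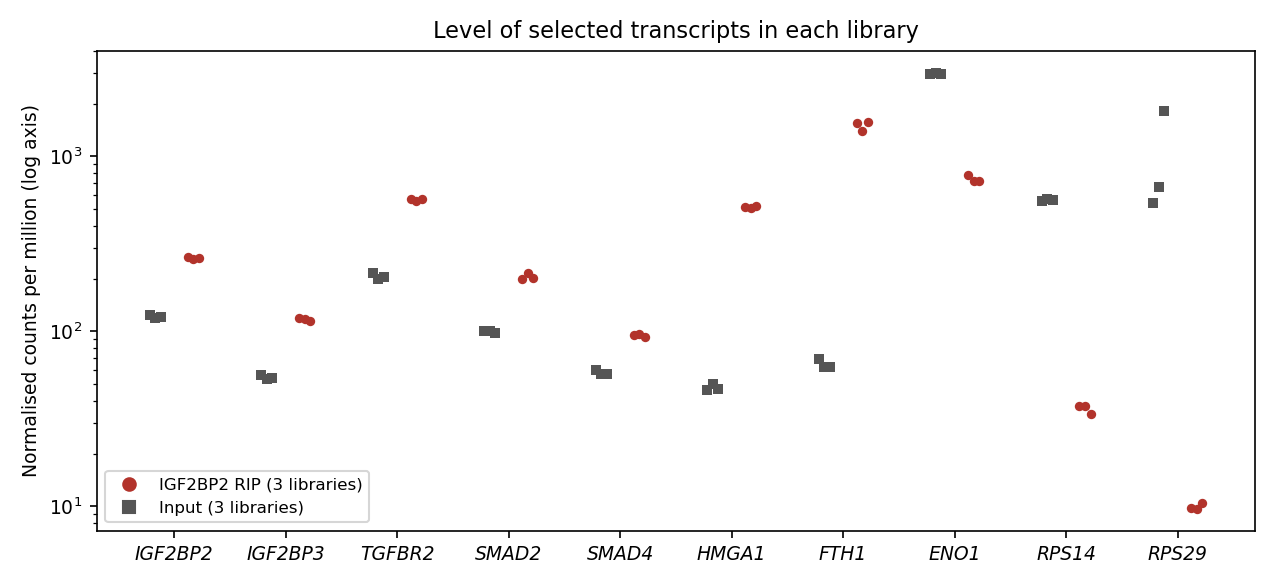
Normalised CPM (log axis) of 10 transcripts in each of the 3 IGF2BP2 RIP libraries (red circles) and 3 input libraries (grey squares). The groups do not overlap for any of the 10, and the inputs of *RPS29* spread far more widely than those of the other transcripts.

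Transcripts of TGF-beta and SMAD signalling were mostly higher with IGF2BP2. Of the 44 tested components and direct regulators of the pathway, 27 were enriched, 10 were depleted and 7 did not pass the test, with 27 and 10 adjusted over the list alone. With library size alone as the scale 22 were enriched and 14 depleted. The list's median length was 5849 nt. With TMM scaling, 54.1% of all tested genes of 4690 to 6769 nt were enriched and 28.5% depleted. *TGFBR2*, the type II TGF-beta receptor (chromosome 3, 30606356 to 30694142), rose 2.74-fold, from 206 ± 8.74 to 564 ± 7.95 CPM (log2 fold change 1.45, SE 0.037, edgeR adjusted p = 8.27e-21). *TGFBR1*, the type I receptor (chromosome 9, 99103647 to 99154192), rose 1.30-fold, from 51.3 ± 2.11 to 66.7 ± 1.19 CPM (edgeR adjusted p = 1.39e-07). Among the SMADs that carry the TGF-beta signal, *SMAD2* (chromosome 18, 47808957 to 47930872) rose 2.07-fold to 206 ± 9.04 CPM and *SMAD3* (chromosome 15, 67065602 to 67195169) rose 1.28-fold to 278 ± 10.1 CPM. *SMAD4*, their common partner (chromosome 18, 51030213 to 51085042), rose 1.63-fold to 94.6 ± 2.03 CPM. Among members with a mean of at least 5 CPM the highest folds were those of *SMAD9*, at 3.52-fold, and of the ligand *TGFB3*, at 3.20-fold but only 9.97 ± 0.114 CPM. The lowest were those of the inhibin subunit *INHBB*, which was 1.77-fold lower, and of *LTBP4*, which encodes a latent TGF-beta binding protein and was 1.68-fold lower.

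As a set, the pathway components ranked above the other genes in limma's camera test with its preset correlation (adjusted p = 0.0259), and the median log2 fold change of the list was 0.37. The call was lost with an estimated correlation (adjusted p = 0.269). It was also lost when the trend of enrichment with gene length was removed (adjusted p = 0.465), and over all camera alternatives the adjusted p ran from 0.01004 to 0.465. In the length-corrected fit the list had 21 enriched and 14 depleted members, *TGFBR2* kept a log2 fold change of 1.31 and *SMAD2* one of 0.53, while *TGFBR1* (0.01) and *SMAD3* (-0.066) no longer passed the test.

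**Figure D2:**
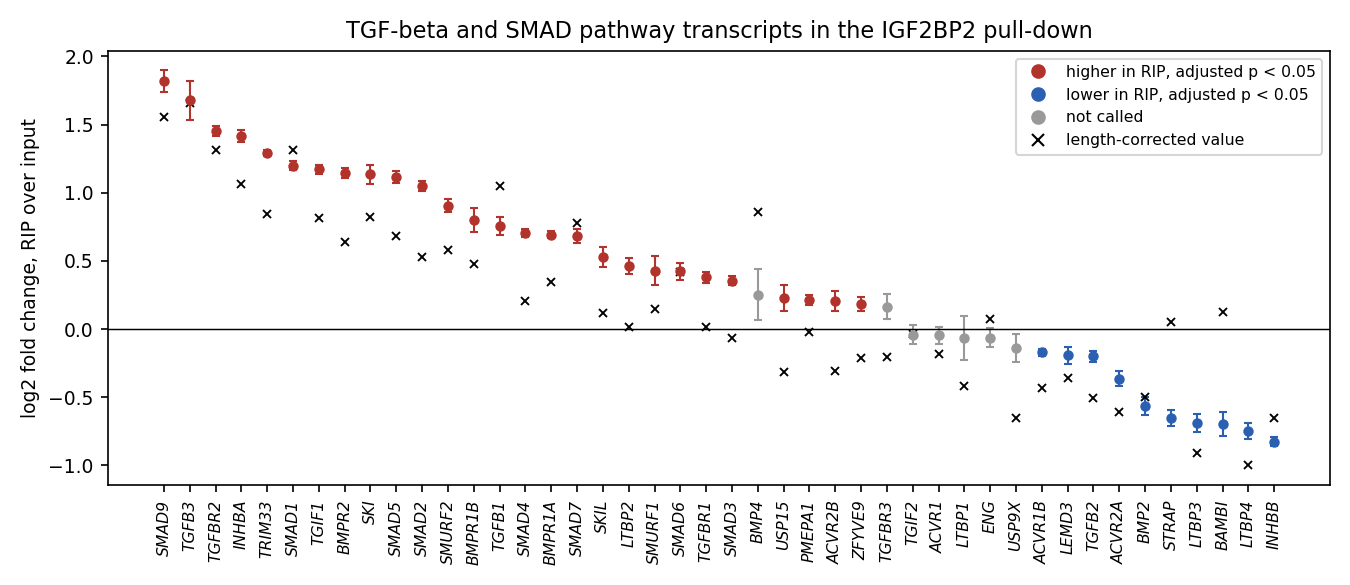
Log2 fold change of RIP over input for the 44 tested TGF-beta and SMAD pathway transcripts, ordered by size. Points are edgeR estimates with bars of 1 SE from the spread between libraries, red where enriched, blue where depleted and grey where not called, and crosses are the values after removal of the length trend, which lie lower for most members.

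Genes that respond to TGF-beta at the level of transcription showed no common direction. Of 27 tested, 11 were enriched, 13 depleted and 3 not called (12 and 13 adjusted over the list alone), and the list did not pass the set test (camera adjusted p = 0.791). *SNAI2*, a transcription factor of epithelial-mesenchymal transition, was 3.26-fold higher in RIP and the basement membrane collagen *COL4A1* 1.73-fold higher. *ID3* was 4.87-fold lower and the matricellular gene *CCN1* 2.66-fold lower.

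Transcripts named in earlier work as targets of the IGF2BP family went both ways. Among 20 tested, 11 were enriched, 6 depleted and 3 not called, with a median log2 fold change of 0.69 and a camera adjusted p of 0.278. *HMGA1*, which encodes a chromatin architectural protein (chromosome 6, 34236873 to 34246231), rose 10.7-fold from 47.8 ± 2.05 to 513 ± 8.64 CPM. *PABPC1*, the cytoplasmic poly(A)-binding protein, rose 4.91-fold and reached 10999 ± 239 CPM. *MARCKSL1* was 3.09-fold lower and *CDC34* 3.05-fold lower. Members chosen after their values were seen were *HMGA2* and *MYC*: *HMGA2* had a log2 fold change of 1.96 (SE 0.034) and *MYC* one of -0.68 (SE 0.054). *IGF2*, for which the family is named, had at most 13 reads in a library and was not tested.

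The m6A machinery also moved in both directions, with 11 of 21 members enriched, 7 depleted and 3 not called (camera adjusted p = 0.580). Its median log2 fold change, 0.16, was -0.078 with library size alone as the scale, where 8 were enriched and 9 depleted. The demethylase *FTO* rose 3.09-fold and *CBLL1*, a component of the methyltransferase complex, 2.68-fold. The catalytic methyltransferase *METTL3* was 2.01-fold lower, and *HNRNPA2B1*, an RNA-binding protein linked to m6A, was 3.31-fold lower.

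Genes of the hypoxia response and of clear cell renal carcinoma numbered 16 enriched, 14 depleted and 1 not called out of 31 (camera adjusted p = 0.613). The carbonic anhydrase *CA12* rose 5.12-fold and the prolyl hydroxylase *EGLN1* 3.60-fold, whereas *ADM* was 2.67-fold lower and *ANGPTL4* 2.37-fold lower. Glycolytic enzymes were 5 enriched, 10 depleted and 2 not called (camera adjusted p = 0.464). Lactate dehydrogenase *LDHA* rose 2.51-fold and *GPI* 1.95-fold, while *ENO1* was 4.0-fold lower and *TPI1* 3.91-fold lower.

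Most mRNAs for ribosomal proteins, the respiratory chain and histones were depleted. Of 78 cytosolic ribosomal protein genes, 73 were depleted, 4 enriched and 1 not called, with a median log2 fold change of -1.86. After removal of the length trend 63 were depleted and 11 enriched, with a median of -1.01. *RPS14* was 15.6-fold lower (36.2 ± 2.03 CPM in RIP, 564 ± 6.55 in input), while *RPS27* rose 2.23-fold and *RPL39* 1.24-fold, although *RPL39* did not pass the test with library size alone as the scale, where 1 member was enriched and 74 depleted. *RPS29* was 101-fold lower, but its inputs spread from 15291 to 50867 reads, and without input replicate 3 it was 61.0-fold lower. Of 17 other mRNAs with a 5' terminal oligopyrimidine tract, 13 were depleted, among them the elongation factor subunits *EEF1B2*, 3.37-fold, and *EEF1D*, 2.82-fold. The 4 enriched members included *PABPC1* and *EEF2*, which rose 2.04-fold, and with library size alone as the scale 2 were enriched and 14 depleted. In camera the ribosomal protein list gave an adjusted p of 1.08e-14 and the other oligopyrimidine mRNAs one of 0.0259. With an estimated correlation these became adjusted p = 0.269 and 0.394.

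Nuclear-encoded subunits of the respiratory chain and ATP synthase were depleted in 70 of 79 cases and enriched in 7, with a median log2 fold change of -1.35. After removal of the length trend 49 were depleted and 21 enriched, with a median of -0.67. *NDUFC2* was 18.3-fold lower and *NDUFB11* 14.8-fold lower, both subunits of complex I. *UQCRC2* and *COX7B* went the other way, at 1.70-fold and 1.67-fold higher. Replication-dependent histones were depleted in 55 of 58 cases, with a median log2 fold change of -1.92. *H4C4* was 16.9-fold lower and *H3C10* 12-fold lower, and the 2 enriched members were *H4C3*, at 2.58-fold, and *H2AC16*, at 1.64-fold. Histone genes exist in near-identical copies whose reads the counting can split, so single histone genes are uncertain. Replication-dependent histone mRNAs lack a poly(A) tail, while the labels give the RNA as poly(A) RNA. How they entered the libraries was not examined, so the depletion of this list need not reflect IGF2BP2. The camera adjusted p was 1.33e-10 for the respiratory chain and 9.73e-13 for histones, and with an estimated correlation adjusted p = 0.269 for each. After removal of the length trend 31 histones were depleted and 18 enriched, with a median of -0.44, and the list no longer passed (adjusted p = 0.104).

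The 13 mRNAs encoded by the mitochondrial genome were divided. Of these, 4 were enriched, 3 depleted and 6 not called (camera adjusted p = 0.867). The median log2 fold change was 0.11 but the mean -0.049, and with library size alone as the scale the median was -0.13, with 3 enriched and 8 depleted. After removal of the length trend all 13 were enriched and the list ranked above other genes in camera with the preset correlation (adjusted p = 0.000241). An estimated correlation was used without the length correction only, where the list did not pass camera (adjusted p = 0.971). With the length trend removed *MT-ND3* and *MT-CO2* turned to 0.31 and 0.19. *MT-ND4L* rose 2.18-fold and *MT-CYB* 1.58-fold, while *MT-ND3* was 3.27-fold lower and *MT-CO2* 2.58-fold lower.

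Proliferation genes were depleted in 24 of 30 cases, enriched in 3 and not called in 3, with a median log2 fold change of -0.76 (camera adjusted p = 0.000362, and adjusted p = 0.269 with an estimated correlation). *PCNA*, the replication clamp, was 7.05-fold lower and the mitotic kinase *AURKB* 4.37-fold lower. *FOXM1*, a transcription factor of mitotic genes, rose 2.08-fold and the cyclin *CCNA2* 1.4-fold. Numbered zinc finger genes moved the other way, with 254 of 436 enriched, 70 depleted and 112 not called (253 and 70 adjusted over the list alone, 212 and 109 with library size alone as the scale) and a median log2 fold change of 0.49 (camera adjusted p = 3.84e-05, and adjusted p = 0.269 with an estimated correlation). *ZNF213* rose 9.86-fold and *ZNF865* 5.92-fold, while *ZNF768* was 4.48-fold lower and *ZNF622* 4.05-fold lower.

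**Figure D3:**
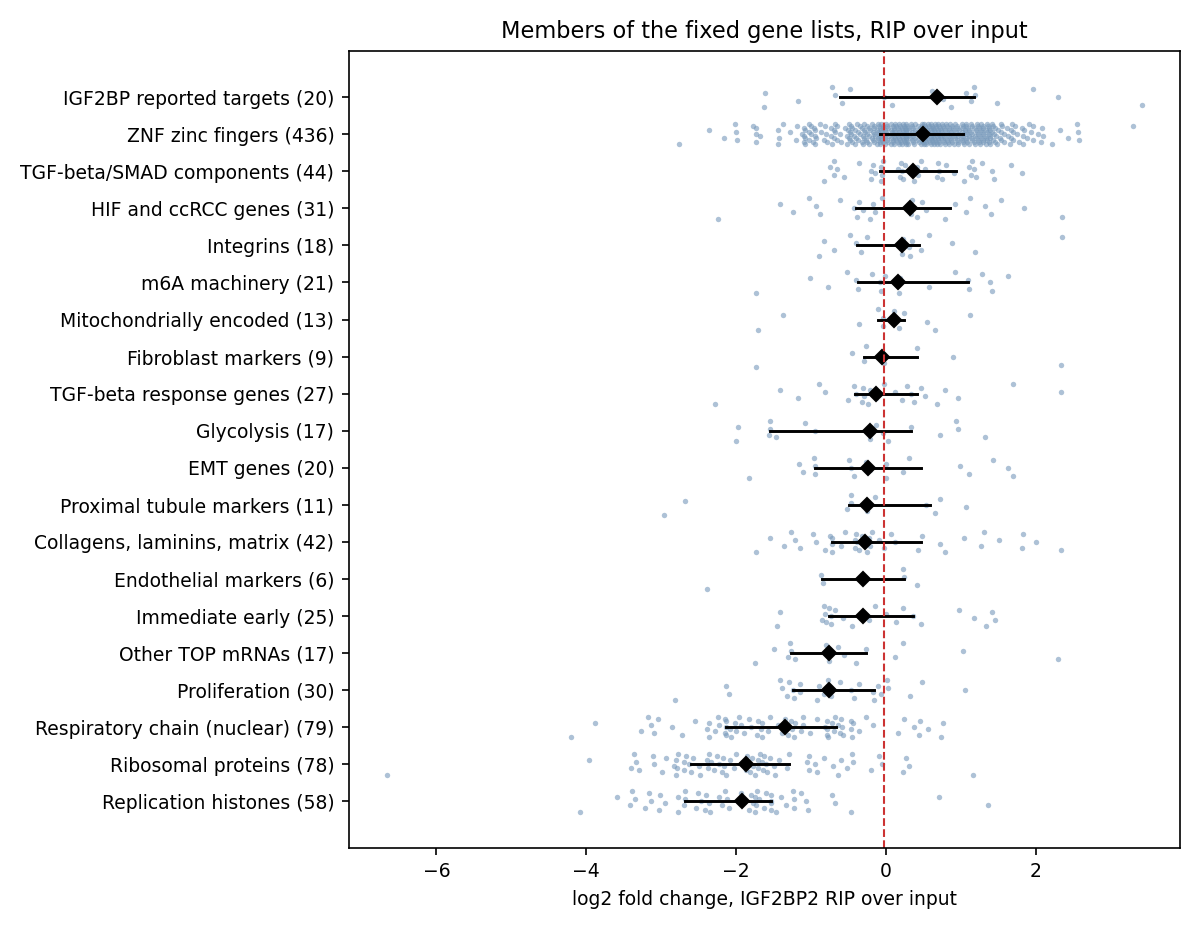
Log2 fold change of RIP over input for the members of each fixed gene list with at least 5 tested members (blue points, number of members in brackets). Black diamonds are medians, black bars the quartiles of the members, and the dashed red line is the median of all tested genes. Histones, ribosomal proteins and the respiratory chain have the lowest medians, at -1.92, -1.86 and -1.35.

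Adhesion, matrix and early response genes showed no common direction. Collagens, laminins and related matrix genes were 12 enriched and 22 depleted of 42 (camera adjusted p = 0.580). After removal of the length trend the list passed camera as lower with the preset correlation (adjusted p = 0.0340). An estimated correlation was used without the length correction only, where camera gave an adjusted p of 0.952. *COL5A1* was 2.85-fold and *COL27A1* 2.48-fold higher, and *COL13A1* 2.56-fold and *LAMB3* 2.41-fold lower. Integrins were 9 enriched and 5 depleted of 18 (8 and 5 adjusted over the list alone, camera adjusted p = 0.613), and their median log2 fold change of 0.22 was -0.018 with library size alone as the scale, with *ITGB8* 2.29-fold and *ITGB6* 1.84-fold higher and *ITGA3* 1.85-fold and *ITGB1* 1.4-fold lower. Genes of epithelial-mesenchymal transition were 6 enriched and 11 depleted of 20 (camera adjusted p = 0.719, lower, although fry placed the list higher). *ZEB1* rose 3.11-fold, the keratin *KRT19* was 2.15-fold lower, a call that ended after removal of the length trend (-0.089), and the matrix protease *MMP14* 1.95-fold lower. Immediate early genes were 8 enriched and 13 depleted of 25 (camera adjusted p = 0.613), with *ZFP36L1* 2.75-fold and *EGR1* 2.66-fold higher and *IER5* 2.73-fold lower. *TUG1*, the only tested member of a list of nuclear long noncoding RNAs, rose 3.43-fold, and the reference table lists it as protein-coding.

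Most markers of endothelial, immune and fibroblast cells had low levels, with *CD68* the exception. None of the 11 endothelial markers in the table was above 4.67 CPM in any library before TMM scaling, and of the 6 tested 1 was depleted (3 with library size alone as the scale) and 5 were not called (camera adjusted p = 0.791). *TIE1* stood at 3.88 ± 0.841 CPM in RIP and 3.25 ± 0.970 in input, passing the test only without input replicate 1 (log2 fold change 0.50), and *PECAM1* at 2.21 ± 0.113 and 1.88 ± 0.263. Of 16 immune and blood markers 3 had enough reads to be tested, of which 2 were enriched and 1 not called. *CD68*, a lysosomal protein found in macrophages and other cells, rose 2.78-fold, from 43.6 ± 1.03 to 121 ± 4.47 CPM, and *CSF1R* 2.29-fold, from 4.99 ± 0.656 to 11.4 ± 0.232 CPM. Fibroblast markers were 3 enriched and 6 not called of 9 (2 enriched and 3 depleted with library size alone as the scale, camera adjusted p = 0.816), with a median log2 fold change of -0.050 where camera ranked the list higher, and *THY1* rose 1.87-fold at 7.61 ± 0.501 CPM. Proximal tubule markers, the lineage from which this carcinoma is thought to arise, were 3 enriched and 2 depleted of 11 (camera adjusted p = 0.953), with a median log2 fold change of -0.24 where camera ranked the list higher. The kidney transcription factors *PAX2* and *PAX8* rose 2.10-fold and 1.66-fold, and the aminopeptidase *ANPEP* was 1.38-fold lower.

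Among called genes with a mean of at least 5 CPM and no overlap between groups, the most enriched transcripts were *LRP11* at 25.6-fold (chromosome 6, 149818757 to 149864359) and the ferritin heavy chain *FTH1* at 23.2-fold (chromosome 11, 61964285 to 61967634). *LRP11* stood at 46.5 ± 7.27 CPM in RIP and 1.81 ± 0.129 in input, and *FTH1* at 1503 ± 99.3 and 64.7 ± 3.78. *HMGA1* and *ZNF213* followed, then the FGF receptor-like gene *FGFRL1* at 8.20-fold, *PLBD2* at 7.66-fold, the mitochondrial carrier *SLC25A23* at 6.96-fold, *PABPC3* at 6.65-fold, the TFIID subunit *TAF6* at 6.54-fold and the F-box gene *FBXL7* at 6.51-fold. *PABPC3* is an intronless copy of *PABPC1* and can share reads with it. After *RPS29* and *NDUFC2*, the most depleted were *UBL5* at 17.1-fold, *H4C4*, *PTTG1* (securin) at 16.6-fold, the actin-binding thymosin *TMSB10* at 16.4-fold, *RPS14*, *NDUFB11*, and the selenoproteins *GPX4* at 14.4-fold and *SELENOH* at 13.8-fold. *TMSB10* fell from 2277 ± 68.4 CPM in input to 139 ± 7.58 in RIP. In each of these 20 genes all 3 RIP libraries lay beyond all 3 inputs, and the edgeR adjusted p was 0.00103 for *RPS29* and at most 2.09e-14 for the other 19.

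Enrichment followed gene length. In the shortest of 5 equal groups of the tested genes (exonic length 207 to 2223 nt) the median log2 fold change was -0.98, with 16.1% enriched and 69.0% depleted. It rose through -0.35, 0.02 and 0.29 in the groups between to 0.49 in the longest (6769 to 116859 nt), where 63.7% were enriched and 20.5% depleted. Spearman's rho across genes was 0.44, and 0.43 to 0.44 with each RIP library taken alone, although genes are not independent replicates. The relation to mean CPM was weaker, at a rho of 0.18. This mean includes the RIP libraries, so a gene high in RIP raises both values and part of the relation is built in. In 5 equal groups by mean CPM the median log2 fold change was -0.077 in the lowest, -0.38 in the next and 0.47 in the highest. Ribosomal protein genes had a median length of 1442 nt, TGF-beta and SMAD components one of 5849 nt and all tested genes one of 3981 nt.

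**Figure D4:**
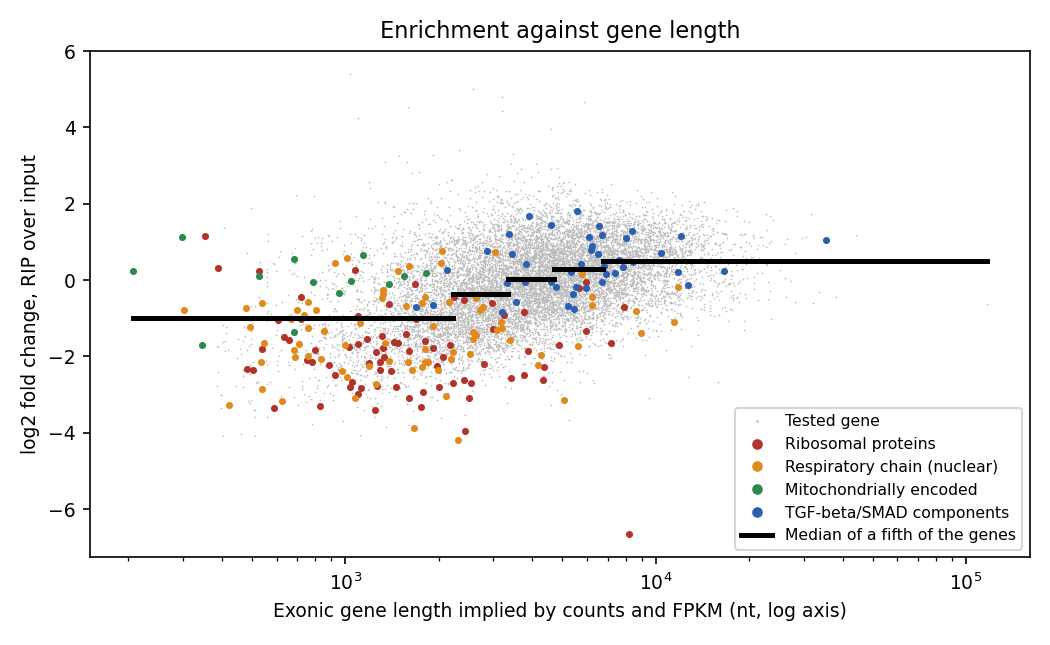
Log2 fold change of RIP over input against exonic gene length in nucleotides (log axis) for each of the 12856 tested genes (grey points), with 4 gene lists in colour. Black bars are the medians of 5 equal groups by length, which rise from -0.98 to 0.49, and most mitochondrially encoded mRNAs lie above the bar of the shortest group.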

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

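Over 122 results, 2303 of 2379 values under the alternatives kept their direction and side of the threshold, or for counts stayed within 1.5 times of the reported count, and of 1924 values of single named genes 1899 did. Same-numbered RIP and input libraries had correlations of 0.036, -0.046 and 0.035 between their deviations from the group means. Only RIP library 1 correlated best with its own number, so no pairing was seen. The labels do not say whether same-numbered libraries share a source, and these values cannot settle it. The replicate block gave 5210 enriched and 5390 depleted genes and changed no call among the results, though the fibroblast list, not called, turned lower (0.970). By its construction the test against a 1.5-fold change called fewer genes, 2973 enriched and 3358 depleted. Among TGF-beta and SMAD components it called 17 enriched and 3 depleted. It also ended the calls of *TGFBR1*, *SMAD3*, *RPL39*, *ITGB1*, *CCNA2* and *ANPEP*. *RPL39* did not pass in the fits on log2 FPKM or with library size alone as the scale either. FPKM values are scaled by library totals too, so these fits are not separate checks. Genes enriched 2-fold or more numbered 1194 with library size alone as the scale, 672 with log2(FPKM + 1), 910 with log2(FPKM + 0.1) and 675 with unfiltered log2(FPKM + 1), against 1943. DESeq2 gave 5154 enriched and 5132 depleted genes, shared 10117 of the 10635 called genes, all in the same direction, and gave no adjusted p for 3534 genes. With an estimated correlation no list passed camera. The adjusted p was 0.269 for TGF-beta and SMAD components, the respiratory chain, ribosomal proteins, histones, proliferation and zinc finger genes. For the other oligopyrimidine mRNAs it was 0.394. Before adjustment the camera p of these lists ran from 0.0308 for zinc finger genes to 0.141 for the other oligopyrimidine mRNAs. This setting has few degrees of freedom with 6 libraries, so it cannot show whether correlation between genes was the cause. With fry, which by construction does not compare a list with other genes, TGF-beta response genes (0.00231) and glycolysis (0.000315) passed as lower, and m6A machinery (2.33e-05), IGF2BP reported targets (8.71e-07), HIF and renal carcinoma genes (2.29e-05) and integrins (0.00231) as higher, while mitochondrially encoded mRNAs turned lower (0.0625) and genes of epithelial-mesenchymal transition higher (0.107), both uncalled. The length correction, without and with the replicate block, ended the call of TGF-beta and SMAD components (adjusted p = 0.465 and 0.440) and of histones (0.104 and 0.135), and brought in mitochondrially encoded mRNAs as higher (0.000241 and 0.000558) and matrix genes as lower (0.0340 and 0.0278). Uncalled either way, integrins turned lower (0.465 and 0.440), immediate early genes higher (0.930 and 0.892) and, with the block only, fibroblast markers lower (0.892). It gave *IGF2BP1* a called log2 fold change of -0.53 in either fit, and turned *SMAD3* to -0.066 and -0.067, *MT-ND3* to 0.31 in either and *MT-CO2* to 0.19 in either. *PECAM1*, never called, turned to -0.13 in either, to -0.0058 with library size alone and to -0.0017 with unfiltered log2(FPKM + 1), and without the low-count filter the proximal tubule list, not called, turned lower (0.774). The rho of enrichment with length, 0.44, was 0.47 with the stricter filter and 0.32, 0.50, 0.40 and 0.35 within groups 1, 2, 4 and 5 of 5 equal groups by mean CPM. Apart from the 1.5-fold test and fry, the cause was not tested. As each library was left out the rho ranged from 0.42 to 0.44, enriched genes from 5103 to 5170 and depleted genes from 5271 to 5348, and no list's call changed. Uncalled results whose direction changed were *IGF2BP1*, from -0.12 to 0.00041, and by adjusted p the proximal tubule list, from 0.832 to 0.992, and the fibroblast list, from 0.633 to 0.991. Without input replicate 1 *TIE1* passed the test at 0.50, and without input replicate 3 *RPS29* went from -6.67 to -5.93, while the other named genes kept their calls and moved by less than 1.5 times.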

Other observations

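The tests of the length trend, of *RPS29* and of the gene families were chosen after the values they bear on had been seen, and the test of other genes rich in pseudogenes was added after the pseudogene numbers of *FTH1* and *HMGA1* were known, with the 8 of *HMGA1* as its minimum.

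Among 31 gene families picked by symbol, some of which share members with the fixed lists, 11 passed camera, and 9 of these also passed after the length correction. With an estimated correlation none of the 31 passed, the lowest adjusted p being 0.233. In these 9 families, depleted genes included 39 of 49 DEAD and DEAH box helicases (median log2 fold change -0.86, 6 enriched), 18 of 22 heterogeneous nuclear ribonucleoproteins (-0.74, with 3 of the 22 also in fixed lists), 9 of 11 SR splicing factors (-1.30), 20 of 23 Sm and LSm proteins (-1.52), 36 of 45 proteasome genes (-1.21), all 9 CCT chaperonin subunits (-1.34) and 14 of 17 aminoacyl-tRNA synthetases (-0.77). Mitochondrial ribosomal proteins were depleted in 60 of 76 cases (-1.35). RAB GTPases of membrane traffic went the other way, with 35 of 53 enriched and 15 depleted (0.61). In camera the 9 had adjusted p values from 5.04e-06 for mitochondrial ribosomal proteins to 0.0221 for RABs, and adjusted p = 0.233 or above with an estimated correlation. After the length correction helicases gave 2.55e-05 and mitochondrial ribosomal proteins 0.0265. Helicases had a median length of 4323 nt and SR factors one of 4079 nt, against 3981 nt for all tested genes, while mitochondrial ribosomal proteins had one of 1614 nt.

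Ribosomal protein, respiratory chain and histone mRNAs were lower with IGF2BP2, and short genes in general were lower too. Against 10000 random lists matched on length, the median of ribosomal protein genes (-1.86) lay below all of them, at a percentile of 0, where matched lists had a median of -0.78. The respiratory chain was also below all of its matched lists, at a percentile of 0 (-1.35 against -0.74), and histones lay at 0.03 (-1.92 against -1.09), so the length trend alone falls short of these changes, with the reserve that genes matched to histones were longer (655 against 494 nt), that the histone call ended under the length correction (median -0.44), and that random lists treat genes as independent, while with an estimated correlation none of the 3 lists passed camera (adjusted p = 0.269 for each). Reads shared with pseudogenes stay open for ribosomal proteins, because the rho of log2 fold change with the number of named pseudogenes was -0.013 and its permutations ran from -0.22 to 0.22. The TGF-beta and SMAD components lay at the 79.9th percentile of their length-matched lists (0.37, matched median 0.24), so the height of that list is consistent with the length of its members, and whether the trend comes from the pull-down or from IGF2BP2 was not tested.

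Other fixed lists were also set against lists matched on length, which like those above treat genes as independent. The reported IGF2BP targets lay at the 98.99th percentile (median log2 fold change 0.69, matched median 0.093), although their set test did not pass (camera adjusted p = 0.278). Zinc finger genes lay at the 100th percentile and mitochondrially encoded mRNAs at 99.8 (with the reserve that genes matched to them were longer, 930 against 784 nt), while proliferation genes lay at 0.48 and the other oligopyrimidine mRNAs at 0.28. With an estimated correlation none of these lists passed camera, with adjusted p = 0.269 for zinc finger and proliferation genes, 0.394 for the other oligopyrimidine mRNAs and the reported targets, and 0.971 for mitochondrially encoded mRNAs, which did not pass with the preset correlation either.

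*FTH1* and *HMGA1*, 23.2-fold and 10.7-fold enriched, have 27 and 8 named pseudogenes, and reads lost to pseudogenes in the inputs alone could raise such genes. Of the 10 most enriched genes 2 had a named pseudogene, which is also the median of draws matched on level. The 119 other genes with at least 8 named pseudogenes, ribosomal proteins left out, had a median log2 fold change of -0.47. That lay at the 1.28th percentile of length-matched lists, so as a class they were lower and not raised. No net rise of genes with many named pseudogenes was seen, but a rise offset by a depletion of other origin would not show. Reads of *FTH1* and *HMGA1* themselves were not examined. The lists were matched on length and not on level. Ribosomal protein genes were also lower, and shared reads stay open for them. An association with IGF2BP2 and GC content both stay open and untested.

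*RPS29*, the most depleted gene, had inputs that differed 3.37-fold, which is at the 100th percentile of 500 genes of similar level, whose median ratio was 1.05, although this spread had prompted the test. Its span on chromosome 14 (49570988 to 49598710) holds *RN7SL1*, the abundant 7SL RNA (49586580 to 49586878). Its exonic length of 8206 nt is long for a small ribosomal protein, but *RPL37* and *RPL14* had 7875 and 7183 nt. The length therefore does not point to *RN7SL1*. Reads of 7SL RNA counted in *RPS29* may have set its input level, but overlap with exons was not examined. 7SL RNA also lacks a poly(A) tail, while the labels give poly(A) RNA. *WDR74* and *C12orf57*, whose spans hold *RNU2-2* and *RNU7-1*, had log2 fold changes of -3.61 and -2.97, while *CLASP1* and *PLCB1*, which hold other small RNAs and were named with them after the values were seen, had 0.48 and 0.35, the last not called.

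The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 10635 genes with edgeR and 1 of the 10 splits reached that count, the real split itself. The highest of the other splits called 0 with edgeR and 0 with limma-voom, with 45 genes at an unadjusted p under 0.05 in each. Every other split mixes RIP and input libraries in both groups, so their difference widens the spread within groups. The low counts follow from this construction and do not measure a rate of false calls.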
